A study of Mus musculus with 8 samples.

How the data were processed

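The measurements are mRNA sequencing libraries of MC38 cells, a mouse colon adenocarcinoma line, in 4 groups of 2 libraries each. The labels call a line made with a CRISPR control WT and a line edited with 1 guide RNA against Piezo2 the knockout (KO). Each line was left non-irradiated or received a single X-ray dose of 30 Gy, and RNA was extracted 60 hours later, per the labels' protocols. Whether the 2 libraries of a group come from separate cultures is not given in the sources used here. The labels describe the RNA as total RNA and the sequencing as mRNA sequencing, and they do not name the library kit.

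The deposited values are the authors' raw read counts per Ensembl gene, whole numbers with no normalization. HISAT2, HISAT, HTSeq and DESeq2 are named in the submitters' processing notes without versions or parameters, and the genome build is mm10 per the same notes. The annotation release, the strand setting, the handling of reads that map to more than 1 place and any filter are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads of near-identical copies (classical and non-classical MHC genes, Ifit3 and Ifit3b, Tgtp1 and Tgtp2, guanylate-binding proteins, histone and ribosomal protein genes) may be split between them, so values of such genes are uncertain. The table listed 29079 genes, 0 of them without a read in every library. A symbol was found for 28880 gene IDs and none for 199, and 28915 were placed on the mm10 (GRCm38) genome with GENCODE M21, whose coordinates are given 1-based.

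Total counts per library ran from 10971004 to 19887180, and between 99.86 and 99.93 percent of them lay in the tested genes. A count of 0 reads was taken to allow up to 3 counts, which is 0.151 to 0.273 counts per M of total counts (CPM) depending on the library. Intervals of folds between groups are 95 percent exact (Clopper-Pearson) intervals on the split of reads. They and the floors cover counting error only, since the reads carry no molecular identifiers. Intervals of medians and median ratios over genes cover the spread between genes instead. The p-values measure only the spread between libraries, which may be technical.

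Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 14923, and libraries were scaled with TMM factors between 0.975 and 1.024. All 8 libraries entered a single fit with 1 coefficient per group and 4 residual degrees of freedom (common dispersion 0.0199). Each gene was tested with the two-sided edgeR quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg (BH) method over the tested genes of a comparison. A gene was called at an adjusted p under 0.05. In the text, "edgeR adjusted p" means this value, and log2 changes are given with the standard error (SE) derived from the F statistic, with 2 libraries in each group. The comparisons were the irradiation effect in WT, the irradiation effect in KO, the KO effect without irradiation, the KO effect after irradiation, and the interaction, which is the irradiation effect in KO minus that in WT. The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined.

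Gene lists were tested with camera (limma 3.58.1), two-sided, with the inter-gene correlation preset at 0.01, and p-values were BH-adjusted within each comparison over the 27 lists with at least 5 tested members. "Camera adjusted p" means this value. Beside it stand camera with the correlation estimated from the residuals, and the number of members past the threshold both over all genes and adjusted over the list alone. The lists reported were p53 target genes; S phase and DNA replication; G2/M and mitosis; DNA double-strand break repair; interferon-stimulated genes; MHC class I antigen presentation; cytosolic nucleic acid sensing; chemokines and cytokines; senescence-associated secreted factors; checkpoint, co-stimulatory and NK cell ligands; YAP/TAZ target genes; mechanosensitive channels and calcium handling; extracellular matrix; ATF4 and unfolded protein response; cholesterol synthesis; glycolysis and hypoxia response; NF-kB target genes; epithelial genes; mesenchymal transition genes; immediate early and heat shock genes; replication-dependent histone genes; mitochondrially encoded genes; cytosolic ribosomal proteins; and markers of macrophages, fibroblasts and endothelium. A list of T and NK cell markers had 1 tested member of 12 in the table and was not tested. A further list that was tested, and some single genes, are not reported here, though adjustments, counts of lists and values over the 4 interferon lists include that list.

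Genes were named by a fixed rule. It took Piezo2, a fixed set of anchor genes, the 6 largest rises and 6 largest falls per comparison among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries, and up to 3 called members per list that passed, with the largest opposite change, or up to 2 called members of a list that did not. Of the genes so named, those printed as examples are mostly ones whose call did not depend on 1 library. Genes chosen after their values were seen are identified as such. Folds against a group without reads are given as bounds against 3 reads over that group, which take the reads of the other group as counted and so lie above the exact 95 percent limit, and folds against 1 to 3 reads carry their counting interval. A list median that changes when such genes are set at their bound is given both ways.

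The labels number the libraries of each group 1 and 2. The deviations of same-numbered libraries from their group means correlated across genes at 0.564 to 0.611 in all 6 pairs of groups, so the numbers were taken to pair the libraries. What the number stands for is not given in the labels. The fit with the replicate number as an additive block is given beside a result where it changes the call or moves a count by over 1.5 times.

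Alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the replicate block, only the compared groups in the fit, a minimum log2 change of 1 (glmTreat), leaving out each library in turn, and fry for the lists. A group left with 1 library was then assumed to vary like the other groups. These fits had no block, so leaving out 1 library also left the replicate difference unbalanced between groups. Settings added after seeing the data were fits without genes of chromosomes 7, 16 and 18, without processed pseudogenes and ribosomal protein genes, and the block without these chromosomes. Upper-quartile scaling and no filter moved the median of all tested genes most, each to 0.09 on the log2 scale in the irradiation effect in WT. Without a filter that median was taken over 29079 genes.

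The steps were tested on simulated counts drawn from the means and library sizes of these libraries, with dispersions and replicate shifts of the fit with the block. Known changes were given to 200 genes with a mean log2 CPM above 2, so the shares below do not cover genes of lower level. For a log2 change of 1, the test without block recovered 76 percent of changed genes in the irradiation effect in WT and 71 percent in the KO effect after irradiation, each among 13995 genes. Among 13963 genes it recovered 73 percent in the irradiation effect in KO, 78 percent in the KO effect without irradiation and 51 percent in the interaction. For a log2 change of 2 the shares were, in the same order, 98, 97, 97, 97 and 85 percent. It made 0 calls among unchanged genes, against 7 to 18 with the block, and called 0 of 26 unchanged lists. Apart from the replicate shifts the genes were drawn independently. The simulation therefore cannot tell how often camera falsely calls lists of correlated genes.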

Results

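Transcripts of MC38 cells, a mouse colon adenocarcinoma line, were counted in 8 libraries. A CRISPR control line (WT) and a line edited against Piezo2 (KO), a mechanically gated ion channel, were each measured without irradiation and 60 hours after 30 Gy of X-rays, with 2 libraries per group. Total counts, in units of 1 M, of replicates 1 and 2 were 16.9 and 15.2 M in non-irradiated WT, 13.6 and 17.2 M in irradiated WT, 11 and 19.9 M in non-irradiated KO, and 15.1 and 17.3 M in irradiated KO. The series title ties Piezo2 in tumour cells to radioresistance and to CD8 T cells, and these libraries hold the tumour cell side of that question.

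Irradiation separated the libraries most. The first principal component of log2 CPM carried 51.6 percent of the variance and ran from -68.87 to -41.15 in non-irradiated and from 30.96 to 77.49 in irradiated libraries. The second carried 24.5 percent and parted WT, at 21.71 to 54.45, from KO, at -52.41 to -24.99. The third, with 13.1 percent, parted replicate 1, at 22.41 to 32.41, from replicate 2, at -35.47 to -25.4, in every group. Correlations of libraries were 0.979 to 0.983 within groups and 0.898 to 0.972 between groups. Mitochondrially encoded genes took 2.17 to 2.91 percent of counts and the 10 most abundant genes 4.34 to 5.34 percent.

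**Figure D1:**
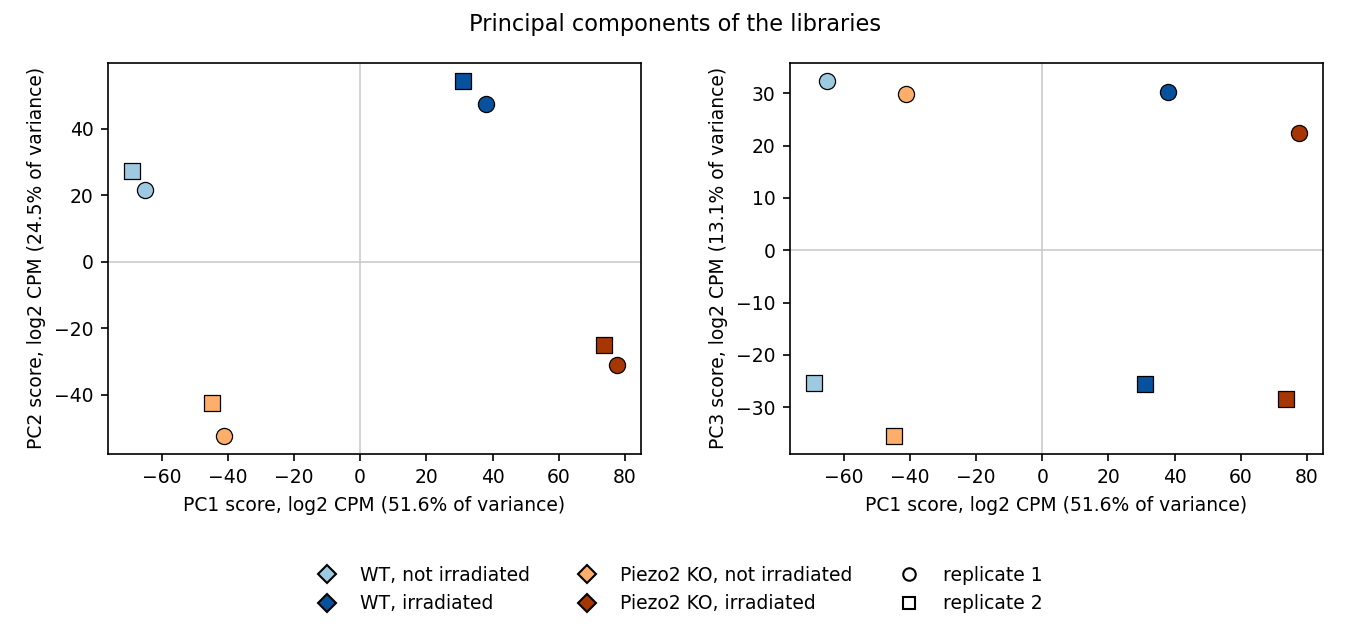
Principal component scores of the 8 libraries in log2 CPM units, with colours for groups and shapes for replicates. PC1 (51.6 percent of variance) orders libraries by irradiation, PC2 (24.5 percent) by line and PC3 (13.1 percent) by replicate number.

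Piezo2 itself (ENSMUSG00000041482, chromosome 18, 63010213 to 63387183, minus strand, protein coding) was close to undetected. It had 0 and 0 reads in non-irradiated WT, 3 and 9 in irradiated WT, 0 and 1 in non-irradiated KO, and 7 and 12 in irradiated KO. In CPM these are 0 and 0, 0.217 and 0.512, 0 and 0.052, and 0.456 and 0.68. Irradiated WT was 4.17-fold above the 3 reads that 0 reads allow in non-irradiated WT, with an exact lower 95 percent limit of 2.9, and irradiated KO was 18.1-fold above non-irradiated KO (95 percent interval 2.88 to 752, from 19 reads against 1). Irradiated KO and irradiated WT had a ratio of 1.5 (0.693 to 3.4), and no fold is given between the non-irradiated lines, which held 1 and 0 reads. The gene fell below the count filter. In the fit without a filter its irradiation effects had edgeR adjusted p = 0.00923 in WT and 0.0159 in KO, while DESeq2 gave adjusted p = 0.0681 and 0.128. Piezo2 mRNA therefore did not separate the lines, and a small insertion or deletion need not lower the mRNA, so these reads do not check the knockout.

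What did 30 Gy do to the control line? The interferon response rose throughout: all 30 tested interferon-stimulated genes were higher, with a median log2 change of 4.16. Isg15, a ubiquitin-like interferon-induced protein, went from 1.30 ± 0.141 to 25.9 ± 5.13 CPM (SD, 2 libraries each). Genes of the mitotic apparatus and MHC class I presentation also rose, while amino acid stress genes of the ATF4 program, glycolytic genes and 5 of 17 replication-dependent histones fell. The lists of the last 3 had adjusted p = 0.0549, 0.247 and 0.352 with an estimated correlation. In all, 3047 of 14923 genes were higher and 2751 lower, of which 1523 and 404 changed at least 2-fold (edgeR quasi-likelihood test, BH-adjusted). The block moved the lower count to 4465, and leaving out non-irradiated WT replicate 1 or irradiated WT replicate 2 moved it to 1741 or 1781. Called genes had a median SE of 0.122.

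Interferon signalling was the broadest change. The interferon-stimulated list (camera adjusted p = 5.89e-80) had 30 members higher and 0 lower, also adjusted over the list alone. Examples were Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), at 4.30 ± 0.20 on the log2 scale (edgeR adjusted p = 1.24e-05), the RNA sensor Ddx58, which encodes RIG-I, at 2.72 ± 0.08 (4.55e-06), and Parp14 at 3.91 ± 0.11 (4.55e-06). Stat2, a subunit of the interferon-activated transcription factor, rose by 2.16 ± 0.08. Irf1 rose by 1.28 ± 0.10 and Il15, a cytokine that sustains T and NK cells, by 1.44 ± 0.22. Socs3, a feedback inhibitor, fell by 0.79. Cd274, which encodes the checkpoint ligand PD-L1, rose by 1.54 ± 0.19 (edgeR adjusted p = 0.000707). Of 18 MHC class I genes 14 were higher and 0 lower, also adjusted over the list alone (median 1.15, camera adjusted p = 1.47e-12). B2m rose by 1.36 ± 0.11 and H2-K1 by 1.11 ± 0.10. The interferon-stimulated and MHC class I lists had adjusted p = 0.032 with an estimated correlation. With the block and an estimated correlation together camera passed 0 of the 27 lists in this and every other comparison, against 14 here without either and 13 with the block alone. Nucleic acid sensing had 9 higher and 1 lower of 17 (10 and 1 adjusted over the list alone; median 0.79, camera adjusted p = 6.21e-06, but adjusted p = 0.0763 with an estimated correlation), among them Ifi203 at 3.30 ± 0.11.

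The largest rises were complement C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136), from 0.158 ± 0.035 to 93.4 ± 8.05 CPM (log2 9.13 ± 0.22, edgeR adjusted p = 2.79e-06), and the lymphoid transcription factor gene Spib at 7.70 ± 0.25 (4.55e-06). Interferon-induced Mx2 was at least 120-fold and Iigp1 at least 103-fold higher, Oas2 307-fold (84.6 to 2540) and Ifi44 207-fold (70.5 to 1010). The largest falls included Mthfd2, a mitochondrial folate enzyme (ENSMUSG00000005667, chromosome 6, 83305691 to 83325908), from 147 ± 4.35 to 21.9 ± 1.05 CPM (log2 -2.75 ± 0.10, edgeR adjusted p = 6.67e-06), the Hedgehog target Gli1 (-2.84 ± 0.46), Etv4 (-2.25 ± 0.12), Tmem238 (-2.68 ± 0.39) and the histone gene Hist1h4i (-2.56 ± 0.30).

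Cell cycle genes moved apart. G2/M and mitosis genes rose, with 19 higher and 0 lower of 26 (22 and 1 adjusted over the list alone; median 0.45, camera adjusted p = 1.34e-06, adjusted p = 0.032 with an estimated correlation). The mitotic kinesin Kif20a rose by 1.45 ± 0.11, Nusap1 by 0.92 ± 0.07, and cyclins Ccnb2 by 0.89 ± 0.07 and Ccnb1 by 0.78 ± 0.14. Replication-dependent histone genes fell, with 0 higher and 5 lower of 17, also adjusted over the list alone (median -1.53, camera adjusted p = 0.00209, adjusted p = 0.352 with an estimated correlation). The nuclear lamina gene Lmnb1 fell as well (-0.44 ± 0.08). The S phase list did not pass (4 higher and 8 lower of 30, also adjusted over the list alone; camera adjusted p = 0.131). Thymidine kinase Tk1 (-1.36 ± 0.07) and Rrm2 (-0.85 ± 0.08) fell. The p53 targets did not move as a list, with 13 higher and 7 lower of 29, also adjusted over the list alone (median 0.14, camera adjusted p = 0.366). Trp53inp1 (3.39 ± 0.19) and Pmaip1 (1.998 ± 0.27) rose, and Cdkn1a, the cyclin kinase inhibitor p21, was at 92.1 ± 6.07 and 101 ± 0.370 CPM (log2 0.14, edgeR adjusted p = 0.194, 0.0158 with the block).

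Secreted, matrix and stress genes followed. Chemokines and cytokines rose, with 12 higher and 1 lower of 19, also adjusted over the list alone (median 1.28, camera adjusted p = 0.000112, adjusted p = 0.0679 with an estimated correlation). The T cell attractant Cxcl10 was at 5.24 ± 0.39, Ccl5 at 3.38 ± 0.43 and Ccl2 at 1.64 ± 0.17, with Vegfa at -0.87. Checkpoint and NK cell ligands rose, with 9 higher and 0 lower of 15 (10 and 0 adjusted over the list alone; median 0.75, camera adjusted p = 0.00341, adjusted p = 0.0763 with an estimated correlation), among them Icam1 at 2.80 ± 0.24 and Tnfsf9 at 1.30 ± 0.17. NF-kB targets rose with 7 higher and 2 lower of 15, also adjusted over the list alone (median 0.70, camera adjusted p = 0.0215, adjusted p = 0.131 with an estimated correlation), including Tnfaip3 at 1.75 ± 0.16. Extracellular matrix genes rose with 11 higher and 0 lower of 23 (12 and 0 adjusted over the list alone; median 0.53, camera adjusted p = 0.000719, adjusted p = 0.54 with an estimated correlation), including fibronectin Fn1 at 2.98 ± 0.13 and Thbs1 at 2.82 ± 0.29. ATF4 and unfolded protein response genes fell with 2 higher and 14 lower of 21 (3 and 14 adjusted over the list alone; median -0.64, camera adjusted p = 3.09e-08, adjusted p = 0.0549 with an estimated correlation). Trib3 fell by 1.86, Shmt2 by 1.36 and Atf4 by 1.19, and Dnajb9 rose by 1.09. Glycolysis and hypoxia genes fell with 2 higher and 12 lower of 20 (2 and 13 adjusted over the list alone; median -0.55, camera adjusted p = 4.87e-05, adjusted p = 0.247 with an estimated correlation), including the glucose transporter Slc2a1 (-1.13 ± 0.07) and the lactate exporter Slc16a3 (-1.34 ± 0.09).

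Some genes used as markers of other cell types were higher as well. Of 5 tested macrophage markers (12 in the list) 3 were higher and 0 lower, also adjusted over the list alone (median 3.32, camera adjusted p = 0.00209, 0.0572 with the block, adjusted p = 0.0763 with an estimated correlation), with Cd68, a lysosomal protein, from 3.63 ± 0.055 to 36.2 ± 1.64 CPM. The tested Ptprc, Ctss and Lyz2 had no more than 2 reads in any non-irradiated library. They met the count filter only through irradiated libraries, so they could hardly come out lower. All 7 tested fibroblast markers (11 in the list) were higher, also adjusted over the list alone (median 3.53, camera adjusted p = 3.09e-08, adjusted p = 0.032 with an estimated correlation), with decorin, Dcn, from 1.75 ± 0.202 to 38.2 ± 2.79 CPM. The pan-leukocyte Ptprc was 20.9-fold higher (5.41 to 178), on 20 reads in each irradiated library, with a log2 change of 4.17, or 7.36 without non-irradiated WT replicate 2. Macrophage C1qa stayed at no more than 1 read, Tyrobp and the T cell gene Cd3e at no more than 2, and fibroblast Lum at no more than 1 in any library.

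The other lists did not pass in WT. DNA double-strand break repair had 6 higher and 4 lower of 26 (7 and 5 adjusted over the list alone; camera adjusted p = 0.566), with the damage kinases Atm (0.69 ± 0.09) and Chek2 (0.72 ± 0.10) called. Mechanosensitive channels and calcium handling had 2 higher and 6 lower of 23, also adjusted over the list alone (0.295), epithelial genes 2 and 0 of 7 (median 0.92, or 0.59 with bounds; 0.197), and mesenchymal genes 4 and 1 of 16 (6 and 3 adjusted over the list alone; 0.591). Immediate early and heat shock genes had 5 higher and 6 lower of 15 (0.591) and endothelial markers 2 and 0 of 5 (0.0807), both also adjusted over the list alone. The remaining lists, with the same test, were senescence-associated factors (6 and 5 of 15; 0.949), YAP/TAZ targets (2 and 6 of 21; 0.251), cholesterol synthesis (2 and 4 of 22; 0.591), mitochondrially encoded genes (2 and 1 of 13; 0.74) and ribosomal proteins (2 and 5 of 77; 0.566). Adjusted over the list alone the counts were the same for the first 3, and 1 and 1 and 1 and 3 for the last ones. Cholesterol synthesis and immediate early genes had medians of 0.03 and 0.01 and means of 0.08 and 0.07, but a downward test.

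How did the KO line respond to the same dose? It responded in the same direction, with a larger rise of some interferon-stimulated genes. All 30 were higher, with a median of 5.34, and Isg15 went from 3.83 ± 0.106 to 344 ± 24.0 CPM. In the interaction test 11 of the 30 passed, and the list had camera adjusted p = 0.0816 with an estimated correlation. Antigen presentation, mitotic and inflammatory genes rose, and glycolysis, replication, cholesterol synthesis and ribosomal protein genes fell. With an estimated correlation adjusted p = 0.0936 for the mitotic and chemokine lists, 0.113 for NF-kB targets, 0.165 for glycolysis, 0.266 for S phase, 0.113 for cholesterol synthesis (10 of 22 genes lower) and 0.448 for ribosomal proteins (22 of 77 lower). In all 3156 genes were higher and 2771 lower, with 1604 and 417 changed at least 2-fold (edgeR quasi-likelihood test, BH-adjusted). The block moved the lower count to 4417; without irradiated KO replicate 1 the higher count was 2008, and without irradiated KO replicate 2 the lower count was 1738. Median SE of called genes was 0.122.

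The interferon-stimulated list passed with 30 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 3.52e-157, adjusted p = 0.0145 with an estimated correlation). Isg15 rose by 6.48 ± 0.17, Ifit1 by 6.80 ± 0.29 and Ddx58 by 3.93 ± 0.08 (edgeR adjusted p = 5.45e-07, 3.55e-06 and 4.07e-07). Irf1 rose by 2.43 ± 0.10, Il15 by 2.33 ± 0.21, Jak2 by 0.49 ± 0.09 and Nlrc5, an activator of MHC class I transcription, by 2.94 ± 0.10. Cd274 rose by 4.59 ± 0.19 (edgeR adjusted p = 2.85e-06). MHC class I genes rose with 15 higher and 0 lower of 18 (16 and 0 adjusted over the list alone; median 1.80, camera adjusted p = 1.13e-32, adjusted p = 0.0115 with an estimated correlation), led by the peptide transporter Tap1 at 3.96 ± 0.08, with B2m at 1.95 ± 0.11 and H2-K1 at 1.66 ± 0.11. Nucleic acid sensing genes rose with 13 higher and 0 lower of 17, also adjusted over the list alone (median 1.12, camera adjusted p = 2.17e-17, adjusted p = 0.0251 with an estimated correlation), including the RNA editor Adar at 2.44 ± 0.09. The largest rises were interferon-induced GTPases: Gbp6 was at least 473-fold and Gbp10 at least 52.7-fold higher, Tgtp2 rose by 9.50 ± 0.40 and Tgtp1 by 8.72 ± 0.31. The largest falls included Gli1 (-3.02 ± 0.48), the protease receptor F2rl1 (-2.91 ± 0.11), Etv4 (-2.72 ± 0.12) and the Notch modifier Lfng (-2.51 ± 0.14).

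G2/M genes rose with 17 higher and 1 lower of 26 (17 and 2 adjusted over the list alone; median 0.40, camera adjusted p = 0.00161, adjusted p = 0.0936 with an estimated correlation), among them Aurka (0.93 ± 0.09). S phase genes fell with 3 higher and 13 lower of 30, also adjusted over the list alone (median -0.22, camera adjusted p = 0.00622, adjusted p = 0.266 with an estimated correlation), with Tk1 at -1.69 ± 0.07 and Mcm10 opposite at 1.08. Lmnb1 fell by 0.94. Cdkn1a rose by 0.44 ± 0.08 (edgeR adjusted p = 0.00289), and p53 targets as a list did not pass (11 higher and 6 lower of 29, 12 and 6 adjusted over the list alone; camera adjusted p = 0.479). Glycolysis genes fell with 0 higher and 14 lower of 20 (1 and 14 adjusted over the list alone; median -0.71, camera adjusted p = 8.35e-06, adjusted p = 0.165 with an estimated correlation), with Ldha, lactate dehydrogenase, at -1.07 ± 0.11. Cholesterol synthesis genes fell with 0 higher and 10 lower of 22, also adjusted over the list alone (median -0.29, camera adjusted p = 0.00561, adjusted p = 0.113 with an estimated correlation). Ribosomal protein genes fell with 0 higher and 22 lower of 77 (0 and 15 adjusted over the list alone; median -0.21, camera adjusted p = 0.00434, adjusted p = 0.448 with an estimated correlation). ATF4 genes fell with 3 higher and 9 lower of 21, also adjusted over the list alone (median -0.21, camera adjusted p = 0.00729, adjusted p = 0.2 with an estimated correlation; median -0.36 without non-irradiated KO replicate 1). Asns fell by 1.27 and Ddit3 rose by 1.23. YAP/TAZ targets, which respond to mechanical cues, fell with 4 higher and 11 lower of 21, also adjusted over the list alone (median -0.43, camera adjusted p = 0.0216, 0.0703 without non-irradiated KO replicate 2, adjusted p = 0.448 with an estimated correlation), with Ccn1 at -1.31 ± 0.08.

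Chemokines rose with 14 higher and 1 lower of 19 (15 and 1 adjusted over the list alone; median 1.26, camera adjusted p = 2.99e-05, adjusted p = 0.0936 with an estimated correlation), with Cxcl10 at 7.35 ± 0.34 and Ccl5 at 3.53 ± 0.40. Checkpoint and NK cell ligands rose with 9 higher and 1 lower of 15, also adjusted over the list alone (median 0.85, camera adjusted p = 0.00161, adjusted p = 0.0936 with an estimated correlation), with Lgals9 at 1.84 ± 0.07 and Cd47 at 1.27 ± 0.10. NF-kB targets rose with 10 higher and 1 lower of 15 (median 0.60, camera adjusted p = 0.0126, adjusted p = 0.113 with an estimated correlation) and matrix genes with 12 higher and 1 lower of 23 (median 0.57, camera adjusted p = 0.0126, adjusted p = 0.499 with an estimated correlation), both also adjusted over the list alone, with Tnfaip3 at 2.26 ± 0.17 and Fn1 at 2.52 ± 0.13. All 5 tested macrophage markers, of 12 in the list, were higher, also adjusted over the list alone (median 3.37, or 2.95 with bounds and 5.72 without non-irradiated KO replicate 1, camera adjusted p = 0.00319, adjusted p = 0.0973 with an estimated correlation). Ptprc, Ctss and Lyz2 among them met the count filter only through irradiated libraries, so a rise of these genes was nearly fixed in advance. Fibroblast markers rose with 5 higher and 1 lower of 7 tested, of 11 in the list. Adjusted over the list alone these counts were 6 and 1 (median 2.95, or 2.73 with bounds, camera adjusted p = 0.000137, adjusted p = 0.0973 with an estimated correlation). The other lists had camera adjusted p from 0.0525 to 0.532. The lowest was that of the histone genes (0 higher and 2 lower of 17, median -1.43), which passed with the block (0.0291). Mechanosensitive channels had a median of -0.03 and a mean of 0.10, and immediate early genes a median of 0.07 and a mean of 0.06, both with a downward test.

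How did the lines differ before irradiation? The KO line carried more cholesterol synthesis and interferon-stimulated transcripts and more Cdkn1a, and fewer replication and NF-kB target transcripts. These 4 lists had adjusted p = 0.0697, 0.231, 0.231 and 0.121 with an estimated correlation, and camera then passed 0 lists, against 6 with the preset correlation and 11 with fry. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) was at 169 ± 6.91 CPM against 92.1 ± 6.07 (log2 0.88 ± 0.08, edgeR adjusted p = 0.000369). A set of genes differed almost completely between the lines: calsyntenin Clstn3 was at least 138-fold and butyrylcholinesterase Bche at least 97.4-fold higher in KO, and the adhesion gene Emb at least 290-fold lower. In all 1555 genes were higher and 1416 lower in KO, 469 and 379 of them at least 2-fold (edgeR quasi-likelihood test, BH-adjusted; median SE 0.114). The block moved these counts to 3197 and 3504. They were 839 and 706 without non-irradiated WT replicate 1, 807 and 744 without its replicate 2, 895 and 689 without non-irradiated KO replicate 1, and 937 and 808 without its replicate 2.

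Other large differences were laminin Lama4, 313-fold higher (55.7 to 12400), Shisa8, 81.8-fold higher (27.6 to 399), and Cpeb1, at 6.37 ± 0.46. In the other direction stood Itpkb (at least 109-fold lower), Enpp5 (at least 88.8-fold), Ndp (at least 74.4-fold), Zic5 (at least 74.1-fold) and Nptx1 (365-fold, 124 to 1770). Matrix crosslinking enzyme Loxl2 (-5.12 ± 0.30), Fn1 (-1.92 ± 0.13) and Fbln1 (-6.14 ± 0.23) were lower in KO, while Dcn (2.32 ± 0.17) and the endothelial receptor Tek (5.23 ± 0.72, or 9.61 without non-irradiated WT replicate 1) were higher.

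Interferon-stimulated genes were higher in the KO line, 23 of 30 with 0 lower (24 and 0 adjusted over the list alone; median 1.57, camera adjusted p = 1.57e-23, adjusted p = 0.231 with an estimated correlation). Ifit1 differed by 3.59 ± 0.49, Oas1a by 3.04 ± 0.24, Isg15 by 1.55 ± 0.25 and Parp14 by 1.37 ± 0.12 (edgeR adjusted p = 0.00245, 0.000238, 0.00482 and 0.000339). Levels were low in both lines, with Isg15 at 3.83 ± 0.106 against 1.30 ± 0.141 CPM. Related lists did not pass. Among single genes, the receptor chain Ifngr2 was called lower (-1.36 ± 0.09). MHC class I had 0 higher and 5 lower of 18, also adjusted over the list alone (median -0.15, camera adjusted p = 0.0624), with Tap1 (-0.50 ± 0.08) and Psmb8 (-1.77 ± 0.28) called, while B2m was at -0.07 and Cd274 at -0.05. Nucleic acid sensing had 4 higher and 1 lower of 17 (6 and 2 adjusted over the list alone; 0.0624), with the DNA-sensing adaptor Tmem173, or STING, from 11.8 ± 1.80 in WT to 37.1 ± 0.924 CPM in KO (1.65 ± 0.12, edgeR adjusted p = 0.000185).

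Cholesterol synthesis genes were higher in KO, 14 of 22 with 0 lower (18 and 0 adjusted over the list alone; median 0.56, camera adjusted p = 2.01e-10, adjusted p = 0.0697 with an estimated correlation). Called members included Dhcr7 (0.80 ± 0.07) and Mvd (0.58 ± 0.07). Replication genes were lower, 17 of 30 with 1 higher (21 and 1 adjusted over the list alone; median -0.31, camera adjusted p = 2.57e-06, adjusted p = 0.231 with an estimated correlation). Among them were the helicase subunit Mcm4 (-0.63 ± 0.07) and the licensing factor Cdt1 (-0.64 ± 0.08), with Rrm1 opposite (0.41). NF-kB targets were lower, 7 of 15 with 0 higher (9 and 0 adjusted over the list alone; median -0.63, or -0.41 without non-irradiated KO replicate 2, camera adjusted p = 5.88e-05, adjusted p = 0.121 with an estimated correlation), with Tnfaip2 at -1.31 ± 0.07 and Traf1 at -1.04 ± 0.07. Ribosomal proteins were lower, 10 of 77 with 2 higher (9 and 1 adjusted over the list alone; median -0.24, camera adjusted p = 0.01, 0.0693 and a median of -0.14 without non-irradiated WT replicate 1, adjusted p = 0.648 with an estimated correlation). Chemokines were lower, 4 of 19 with 0 higher, also adjusted over the list alone (median -0.17, camera adjusted p = 0.0488, adjusted p = 0.328 with an estimated correlation), including the membrane-bound chemokine Cx3cl1 (-4.37 ± 0.25). The median was -0.04 without non-irradiated KO replicate 1. That list did not pass with the block (0.0906) or without irradiated WT replicate 1 (0.0606), irradiated WT replicate 2 (0.0577) or non-irradiated KO replicate 2 (0.12).

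Among lists that did not pass, double-strand break repair had 1 higher and 9 lower of 26 (4 and 11 adjusted over the list alone; median -0.24, camera adjusted p = 0.0624, 0.0369 with the block). Matrix genes had 10 higher and 4 lower of 23 (12 and 6 adjusted over the list alone; median 0.42, mean -0.29, upward test, 0.554, 0.0159 with the block). Mechanosensitive channels had 5 higher and 1 lower of 23, also adjusted over the list alone (0.378): Trpv4 was higher (1.33 ± 0.13) and Trpv2 24.4-fold lower (8.03 to 121). The p53 targets had 6 higher and 2 lower of 29 (9 and 5 adjusted over the list alone; median 0.12, mean -0.15, upward test, 0.425), with Pmaip1, or Noxa, called lower (-4.65 ± 0.40). The rest had camera adjusted p from 0.0615 to 0.842. Median and mean had opposite signs for macrophage markers (0.94 and -0.51) and fibroblast markers (1.06 and -0.24), both with an upward test, and histone genes (0.77 and 0.36) and checkpoint ligands (0.03, or 0.06 with bounds, and 0.41) had a downward test.

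What separated irradiated KO from irradiated WT, the contrast closest to the series title? Interferon-stimulated transcripts were higher in KO, 29 of 30 with 0 lower, at a median log2 difference of 3.35. Isg15 stood at 344 ± 24.0 against 25.9 ± 5.13 CPM and Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095) at 54.3 ± 2.97 against 6.82 ± 1.58 CPM. Antigen presentation and nucleic acid sensing genes were higher too, and replication, ribosomal protein and NF-kB target genes were lower. With an estimated correlation adjusted p = 0.0665 for MHC class I, 0.0911 for S phase, 0.289 for ribosomal proteins and 0.12 for NF-kB targets. In all 1980 genes were higher and 1698 lower in KO, 692 and 407 of them at least 2-fold (edgeR quasi-likelihood test, BH-adjusted; median SE 0.115). The block moved these counts to 3761 and 3755. They were 1183 and 891 without irradiated WT replicate 1, 1160 and 921 without its replicate 2, 1101 and 916 without irradiated KO replicate 1, and 1198 and 850 without its replicate 2.

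**Figure D2:**
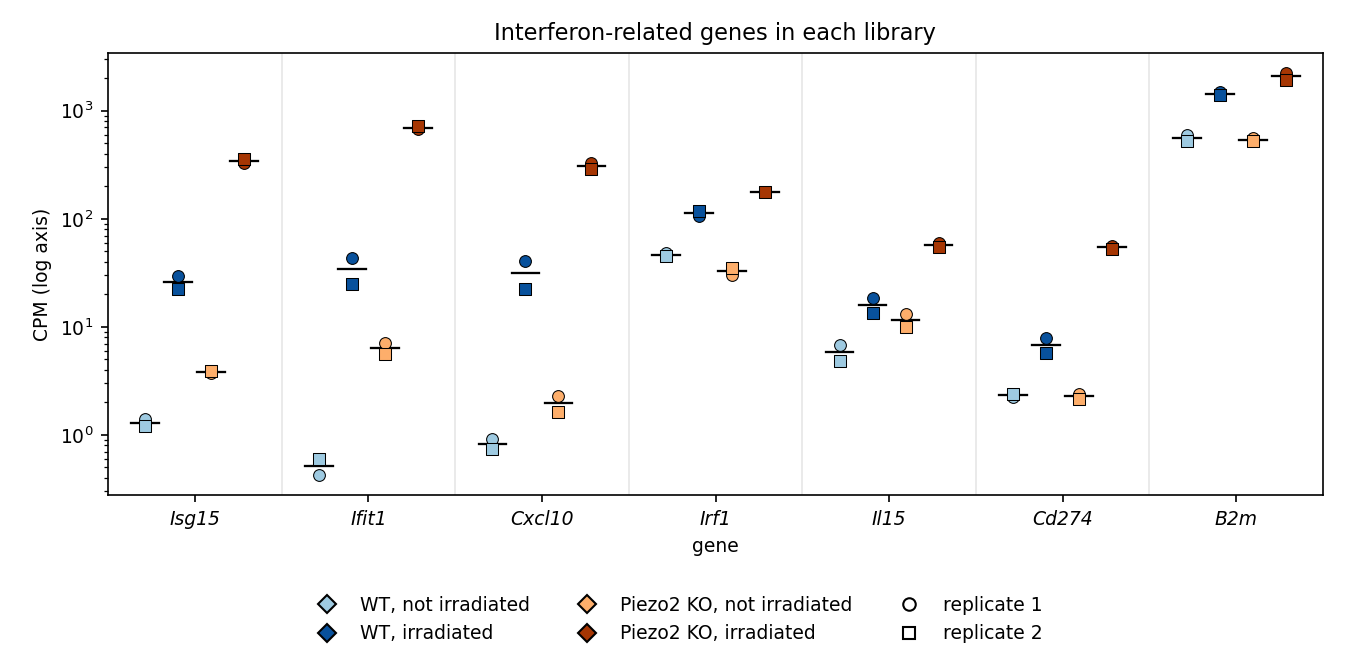
CPM (log axis) of 7 interferon-related genes in each library, with bars at group means, colours for groups and shapes for replicates. Irradiated KO libraries are highest for all 7 genes, with Isg15 at a mean of 344 CPM against 25.9 in irradiated WT.

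The interferon-stimulated list (29 higher and 0 lower also adjusted over the list alone) had camera adjusted p = 6.63e-128 and adjusted p = 0.0306 with an estimated correlation. Isg15 differed by 3.74 ± 0.14, Ifit2 by 3.45 ± 0.10, Oasl1 by 5.30 ± 0.15 and the RNA sensor Ifih1, or MDA5, by 2.92 ± 0.10 (edgeR adjusted p = 7.56e-06 for the first and 6.55e-06 for the others). Further differences were, for Cd274, 2.998 ± 0.17, Il15 1.86 ± 0.20 and Irf1 0.66 ± 0.10, against Ifngr2 at -1.22. MHC class I genes were higher, 10 of 18 with 0 lower (15 and 0 adjusted over the list alone; median 0.54, camera adjusted p = 3.3e-09, adjusted p = 0.0665 with an estimated correlation). Tap1 differed by 2.38 ± 0.08 (edgeR adjusted p = 6.55e-06) and the non-classical H2-T23 by 1.58 ± 0.12. B2m differed by 0.52 ± 0.11 and H2-K1 by 0.55 ± 0.10 (edgeR adjusted p = 0.00962 and 0.00751), and neither passed without irradiated WT replicate 2 (0.0673 and 0.0561) or irradiated KO replicate 1 (0.0829 and 0.0701). Nucleic acid sensing had 11 higher and 1 lower of 17 (12 and 1 adjusted over the list alone; median 1.11, camera adjusted p = 8.54e-16, adjusted p = 0.0329 with an estimated correlation), with the double-stranded RNA sensor Tlr3 at 2.91 ± 0.14 and Ifi203 at 2.47 ± 0.09. Cxcl10 was higher by 3.30 ± 0.25, at 309.9 ± 27.4 against 31.7 ± 13.1 CPM.

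Replication genes were lower in irradiated KO, 17 of 30 with 2 higher (18 and 2 adjusted over the list alone; median -0.46, camera adjusted p = 5.8e-09, adjusted p = 0.0911 with an estimated correlation). Mcm4 was at 154 ± 1.95 against 365 ± 2.93 CPM (-1.24 ± 0.07), Mcm5 at -0.56 ± 0.07, Uhrf1 at -1.02 ± 0.09 and Mcm6 opposite at 0.55. Cdkn1a was higher, at 229.8 ± 5.33 against 101 ± 0.370 CPM (1.18 ± 0.08, edgeR adjusted p = 5.13e-05). Ribosomal protein genes were lower, 29 of 77 with 0 higher (33 and 0 adjusted over the list alone; median -0.47, camera adjusted p = 2.84e-08, adjusted p = 0.289 with an estimated correlation), with Rpl41 at -0.78 ± 0.07. NF-kB targets were lower, 8 of 15 with 1 higher (9 and 1 adjusted over the list alone; median -0.31, or -0.21 without irradiated WT replicate 1, camera adjusted p = 0.00513, adjusted p = 0.12 with an estimated correlation), with Tnfaip2 at -1.17 ± 0.07. Mitochondrially encoded genes were lower, 3 of 13 with 0 higher, also adjusted over the list alone (median -0.55, camera adjusted p = 0.0296, 0.153 and a median of -0.23 without irradiated WT replicate 2 and 0.0958 without irradiated KO replicate 1, adjusted p = 0.472 with an estimated correlation). Cholesterol synthesis genes were higher, 7 of 22 with 0 lower, also adjusted over the list alone (median 0.25, camera adjusted p = 0.0409, adjusted p = 0.289 with an estimated correlation), with Dhcr7 at 0.58 ± 0.07. That list did not pass without non-irradiated WT replicate 1 (0.0518) or 2 (0.0532), irradiated WT replicate 2 (0.101), non-irradiated KO replicate 1 (0.0517) or irradiated KO replicate 1 (0.0993, median 0.15).

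The largest rises in irradiated KO were the copper oxidase gene Heph (145-fold, 39.7 to 1200), the potassium channel gene Kcnk5 (6.74 ± 0.43), Bche (6.65 ± 0.36), Sprr1a (6.60 ± 0.29) and Ifit1bl1 (6.43 ± 0.29). The largest falls were Lhfpl4 (at least 190-fold lower), Ndp (at least 67.4-fold lower), Emb (-8.19 ± 0.20), Thbs1 (-6.82 ± 0.40) and Ncam1 (-6.56 ± 0.25). Complement C3 and Spib, chosen here after their values were seen, were lower in irradiated KO by 1.68 and 2.77 on the log2 scale (edgeR adjusted p = 7.48e-05 and 3.53e-05). The other lists had camera adjusted p from 0.0843 to 0.997. Passing with the block were ATF4 genes (6 higher and 1 lower of 21, 8 and 1 adjusted over the list alone; 0.0843, 0.0344 with the block), G2/M genes (2 higher and 10 lower of 26, also adjusted over the list alone; 0.105, 0.0494 with the block) and matrix genes (10 higher and 4 lower of 23, 11 and 5 adjusted over the list alone; 0.997, 0.0494 with the block). Median and mean had opposite signs for p53 targets (0.25 and -0.005), chemokines (-0.12 and 0.41), matrix genes (0.38 and -0.28), glycolysis genes (0.08 and -0.06), fibroblast markers (0.61 and -0.46) and endothelial markers (-0.06 and 0.68). The test pointed up for p53, matrix and endothelial lists and down for the others, and it pointed down for senescence-associated factors (0.13 and 0.22).

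**Figure D3:**
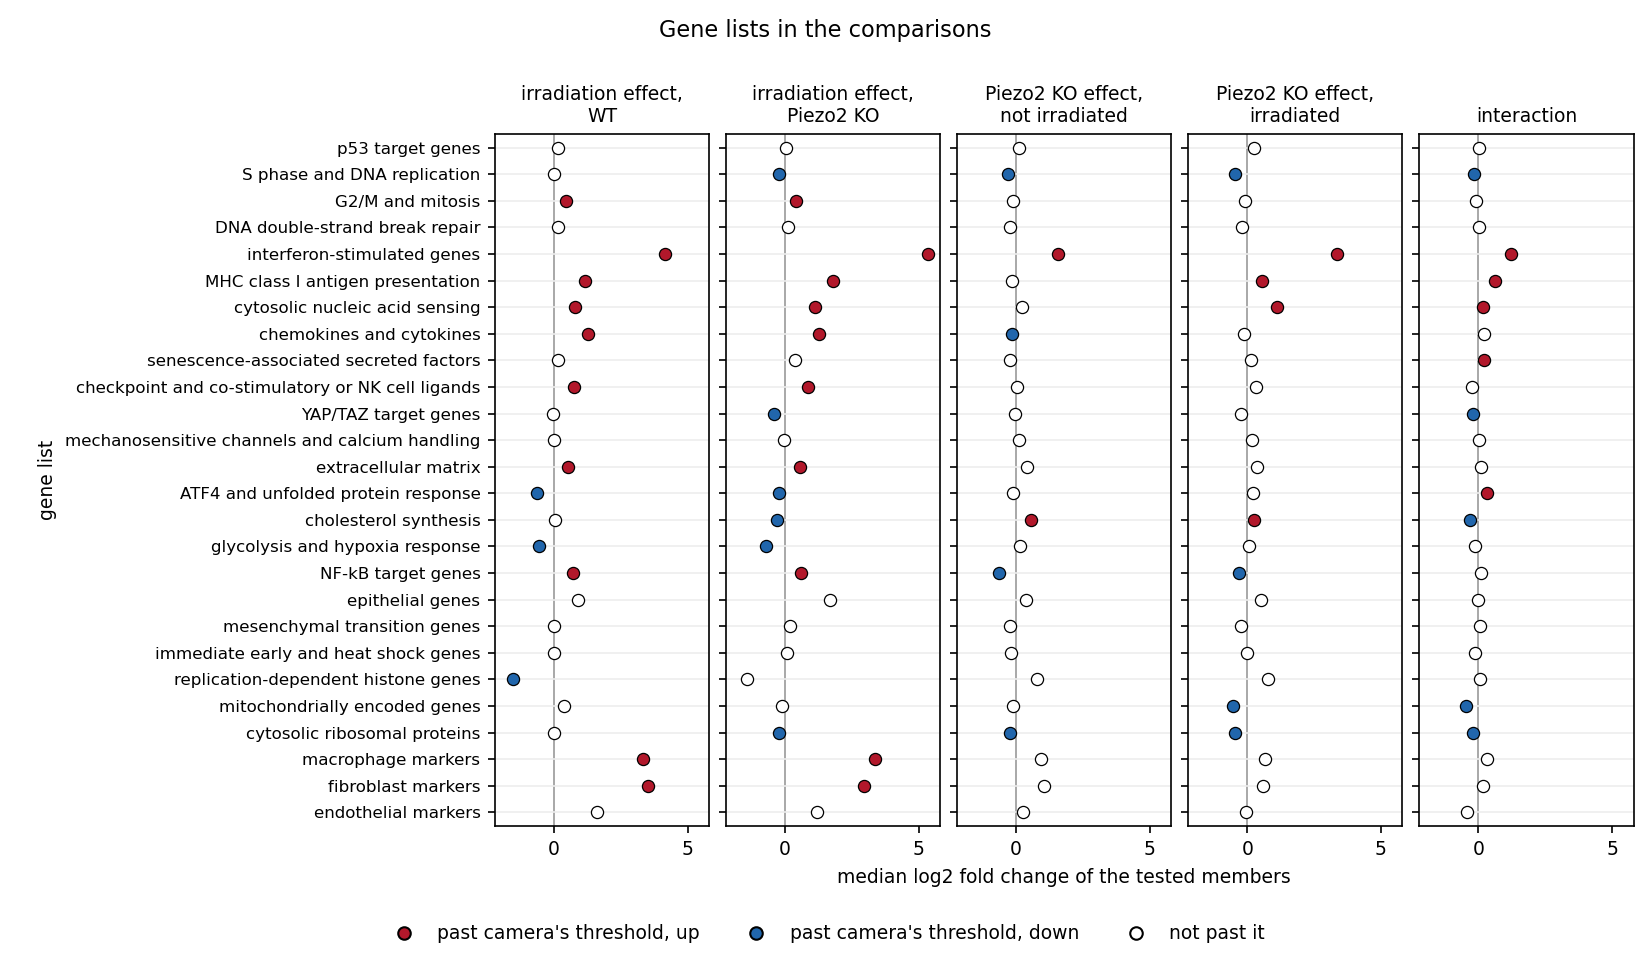
Median log2 fold change of the tested members of each list shown, by comparison, filled red or blue where camera passed upward or downward at an adjusted p under 0.05 and open otherwise. Interferon-stimulated genes have the largest median of the lists that passed in every comparison, from 1.23 in the interaction to 5.34 for irradiation in KO.

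Did the response to irradiation itself differ between the lines? For some interferon and antigen presentation genes it did, with a larger rise in KO. Of 30 interferon-stimulated genes 11 passed, and of 18 MHC class I genes 7, where the lists had adjusted p = 0.0816 and 0.0121 with an estimated correlation. Tap1 (ENSMUSG00000037321, chromosome 17, 34187553 to 34197225) went from 18.2 ± 0.365 to 38.4 ± 1.69 CPM in WT and from 12.9 ± 0.049 to 199.8 ± 1.19 CPM in KO, an interaction of 2.88 ± 0.11 (edgeR adjusted p = 0.000132). Cd274 had an interaction of 3.04 ± 0.27 (0.00213). In all 205 genes had a higher and 85 a lower response in KO, 142 and 46 of them by at least 2-fold (edgeR quasi-likelihood interaction test, BH-adjusted; median SE 0.152). The block moved these counts to 1216 and 1276. Leaving out any 1 of the 8 libraries lowered both counts. They were 106 and 24 without non-irradiated WT replicate 1, 111 and 24 without its replicate 2, 135 and 32 without irradiated WT replicate 1, and 98 and 21 without its replicate 2. In KO they were 110 and 21 without non-irradiated replicate 1, 103 and 29 without its replicate 2, 99 and 21 without irradiated replicate 1, and 102 and 20 without its replicate 2.

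**Figure D4:**
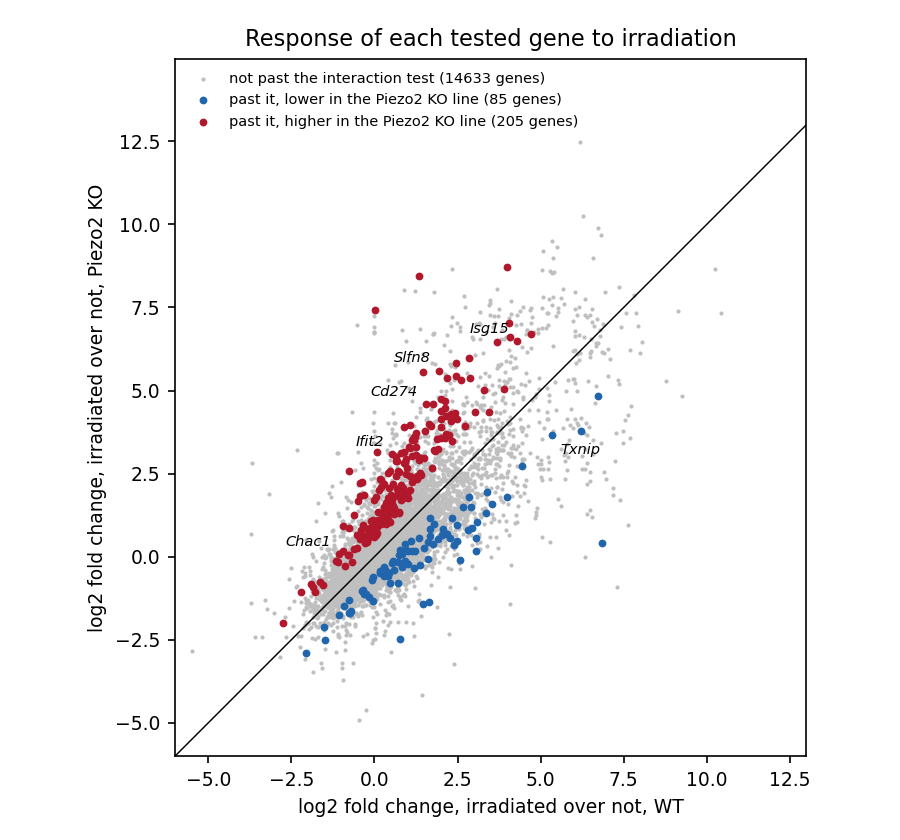
Log2 fold change of each of the 14923 tested genes after irradiation in WT (horizontal) and KO (vertical), with the line of equal response. Red points mark the 205 genes and blue points the 85 genes whose response was higher or lower in KO by the interaction test.

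Of the 205 genes, 189 were called higher after irradiation in KO and 130 in WT, 130 in both, and 180 were higher in irradiated KO than in irradiated WT. Before irradiation 33 were higher and 45 lower in KO. Of the 205, 29 (14.1 percent) were among the 87 tested members of the 4 interferon lists. MHC class I genes had a larger rise in KO, 7 of 18 with 0 lower (15 and 0 adjusted over the list alone; median 0.61, camera adjusted p = 1.31e-31, adjusted p = 0.0121 with an estimated correlation). They included the immunoproteasome subunits Psmb10 (1.35 ± 0.14) and Psmb9 (3.20 ± 0.35). Interferon-stimulated genes had 11 higher and 0 lower of 30 (17 and 1 adjusted over the list alone; median 1.23, camera adjusted p = 7.76e-37, adjusted p = 0.0816 with an estimated correlation). Ifit2 was at 2.56 ± 0.14, Ifih1 at 2.08 ± 0.14 and the RNA-activated kinase Eif2ak2 at 1.67 ± 0.12. Nlrc5 was at 1.99 ± 0.14 and the feedback inhibitor Socs1 at 2.61 ± 0.24. Nucleic acid sensing had 6 higher and 0 lower of 17 (6 and 1 adjusted over the list alone; median 0.16, camera adjusted p = 1.14e-17, adjusted p = 0.026 with an estimated correlation), with Tlr3 at 2.48 ± 0.20 and Samhd1 at 1.22 ± 0.10. The median of that list was 0.29 without non-irradiated WT replicate 2, 0.44 without irradiated WT replicate 1, 0.33 without non-irradiated KO replicate 1 and 0.37 without irradiated KO replicate 2. Irf1 was at 1.16 ± 0.14 (edgeR adjusted p = 0.00661). Isg15, at 2.18 ± 0.31 (0.0138), did not pass without non-irradiated WT replicate 1 (0.13) or 2 (0.0761) or non-irradiated KO replicate 1 (0.0652) or 2 (0.067). Ifit1 (0.76, edgeR adjusted p = 0.771), B2m (0.59, 0.124, 2.82e-12 with the block), H2-K1 (0.55, 0.146, 1.33e-10 with the block), Il15 (0.89, 0.267, 0.000315 with the block) and Jak2 (0.38, 0.231, 0.00377 with the block) did not pass. Cxcl10 (2.11, 0.246, 0.00115 with the block) passed without irradiated WT replicate 1 (0.0197).

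Outside the interferon lists, ATF4 genes fell less in KO, 2 higher and 0 lower of 21 (5 and 0 adjusted over the list alone; median 0.34, camera adjusted p = 9.02e-06, adjusted p = 0.0816 with an estimated correlation), including the glutathione-degrading enzyme Chac1 (1.14 ± 0.11). Cholesterol synthesis genes were shifted down (median -0.33, camera adjusted p = 9.02e-06, adjusted p = 0.0642 with an estimated correlation), as were ribosomal proteins (median -0.22, 1.21e-05, adjusted p = 0.424 with an estimated correlation). Without irradiated WT replicate 1 these medians were -0.20 and -0.14. Single members passing by edgeR numbered 0 of 22 and 0 of 77. At an unadjusted p under 0.05, 8 and 9 of them were lower, and DESeq2 called 1 and 0, limma-voom 0 and 0, and the block 13 and 54. Over the list alone 4 lower cholesterol genes and 0 ribosomal protein genes passed. Among other falls, Pdgfra (-1.14 ± 0.11), the transposon-derived gene Rtl9 (-2.51 ± 0.23) and Slc35f1 (-2.88 ± 0.30) had a lower response in KO, and Slfn8 (3.64 ± 0.34), Lgals9 (1.02 ± 0.10) and the secreted phosphoprotein Spp1 (0.95 ± 0.12) a higher one.

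A group of weaker list calls was lost when certain single libraries were left out of the fit without block. Such a refit also leaves the replicate difference unbalanced between groups. With the block and all 8 libraries, camera adjusted p was 0.00315 for S phase genes, 0.0108 for senescence-associated factors and 0.0222 for YAP/TAZ targets. S phase genes (1 higher and 2 lower of 30, 1 and 4 adjusted over the list alone; median -0.15, camera adjusted p = 0.0252, adjusted p = 0.43 with an estimated correlation) did not pass without non-irradiated WT replicate 2 (0.114), irradiated WT replicate 1 (0.0808, median -0.10) or irradiated KO replicate 2 (0.0985). Senescence-associated factors (1 and 1 of 15, 5 and 2 adjusted over the list alone; median 0.23, camera adjusted p = 0.0439, adjusted p = 0.291 with an estimated correlation) did not pass without non-irradiated WT replicate 2 (0.106), irradiated WT replicate 1 (0.151), non-irradiated KO replicate 1 (0.0594) or 2 (0.0819), or irradiated KO replicate 2 (0.126). Their median was 0.14 without irradiated KO replicate 1. YAP/TAZ targets (0 and 2 of 21, 3 and 5 adjusted over the list alone; median -0.21, camera adjusted p = 0.0439, adjusted p = 0.676 with an estimated correlation) did not pass without non-irradiated WT replicate 1 (0.17), irradiated WT replicate 2 (0.183), non-irradiated KO replicate 2 (0.356) or irradiated KO replicate 1 (0.156), with medians of -0.09, -0.11, -0.07 and -0.08. Mitochondrially encoded genes (median -0.45, camera adjusted p = 0.0439, adjusted p = 0.587 with an estimated correlation) did not pass without the same 4 libraries (0.406, 0.317, 0.264 and 0.171). Their median was then -0.17, -0.12, 0.03 and -0.21, across 0 without non-irradiated KO replicate 2. Of their 13 members edgeR called 0 and limma-voom 0, DESeq2 2 and the block 4, with 3 lower at an unadjusted p under 0.05 and 3 lower adjusted over the list alone. The other lists had camera adjusted p from 0.069 to 0.967, of which G2/M genes (0.069, 0.0174 with the block) and glycolysis genes (0.128, 0.0073 with the block) passed with the block. Median, mean and test direction differed in sign for p53 targets (0.01, 0.14, down), checkpoint ligands (-0.24, -0.11, up), matrix genes (0.09, 0.01, down), epithelial genes (-0.015, 0.12, down), mesenchymal genes (0.06, -0.09, up) and fibroblast markers (0.17, -0.22, down).

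How alike were the effects as a whole? Across the 14923 genes, which are not independent replicates, the log2 changes after irradiation in WT and KO correlated at Pearson r = 0.798 and Spearman rho = 0.796, with a slope of 0.871 and 82.5 percent of genes of the same sign. Genes called higher in both numbered 2208, where independent lists would share 644, those lower in both 2048 (511), and those called in opposite directions 26 (1148). The KO effects without and after irradiation correlated at r = 0.659 and rho = 0.61, with a slope of 0.616 and 74.9 percent of the same sign. Here 1020 genes were higher in both (206), 924 lower in both (161) and 32 called in opposite directions (365). The effects compared share no library.

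Part of the KO effect followed chromosomes, an arrangement examined after the values were seen. Over 10402 protein-coding genes with a mean log2 CPM above 2, chromosome 7 had a median log2 difference of 0.37 without and 0.38 after irradiation (754 genes), chromosome 18, which carries Piezo2, of 0.43 and 0.43 (255 genes), and chromosome 16 of -0.35 and -0.36 (326 genes). The other chromosomes lay between -0.15 and 0.08 without and between -0.16 and 0.11 after irradiation. An exact two-sided permutation test that swapped the lines only within pairs of libraries of the same dose and replicate number gave p = 0.125 for each of these 3 chromosomes, the smallest that 16 swaps allow. It gave the same p for 10 others, so the size of the shift and not the p sets these 3 apart. Chromosome 7 held 334 of the 1555 genes higher in non-irradiated KO (21.5 percent, against 7.7 percent of tested genes), chromosome 18 held 137 (8.8 against 2.4 percent), and chromosome 16 held 140 of the 1416 lower genes (9.9 against 3 percent). Without these chromosomes 2078 genes were called without irradiation, 2812 after irradiation and 268 in the interaction. Of the genes named above, Kif20a and Tmem173 on chromosome 18, Dhcr7 on chromosome 7 and Mcm4 on chromosome 16 are examples and not a full list.

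**Figure D5:**
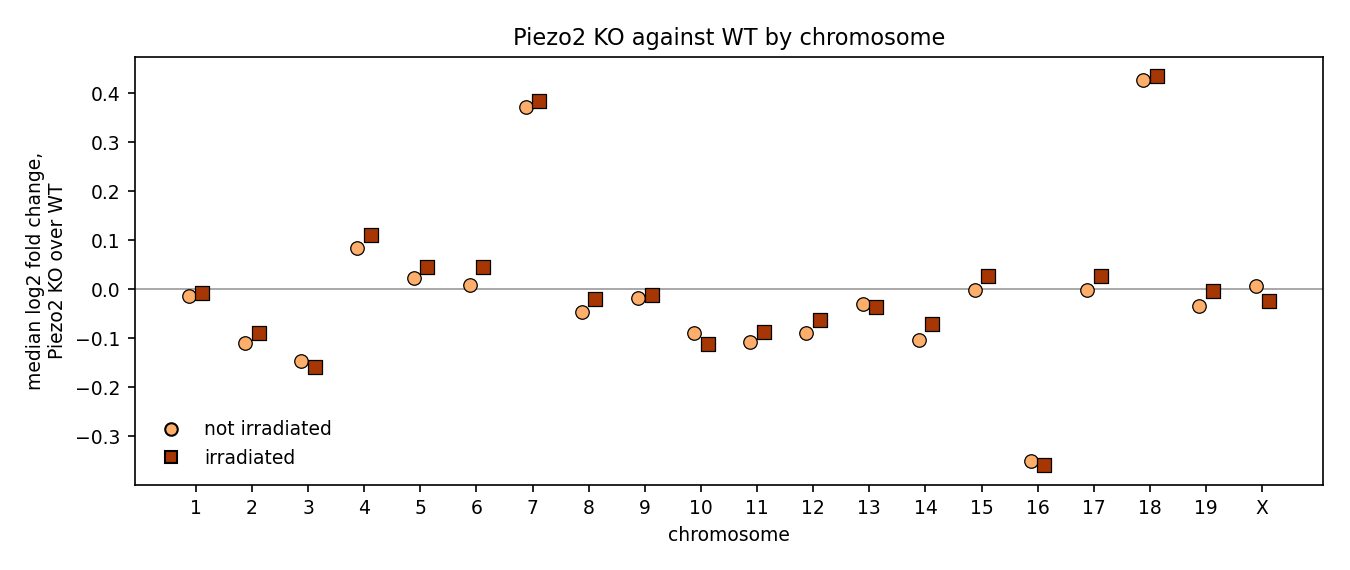
Median log2 fold change of KO over WT for expressed protein-coding genes of each chromosome, without irradiation (circles) and after it (squares). Chromosomes 7 and 18 stand at 0.37 to 0.43 and chromosome 16 at -0.36 to -0.35, apart from the others.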

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

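The interaction test was planned, while all tests of explanations below were chosen only after the results were seen. Each result in this part stands here because the irradiation effect differed between the lines in that test. The counts were 205 genes with a larger and 85 with a smaller change after irradiation in KO. Lists that passed whichever 1 library was left out had median interactions of 1.228 (interferon-stimulated), 0.607 (MHC class I), 0.156 (nucleic acid sensing), 0.339 (ATF4 and unfolded protein response), -0.325 (cholesterol synthesis) and -0.215 (ribosomal proteins). With an estimated correlation the interferon-stimulated, ATF4, cholesterol and ribosomal lists had adjusted p = 0.0816, 0.0816, 0.0642 and 0.424, and ribosomal proteins had 0.107 with fry. The median of nucleic acid sensing was 0.289 without non-irradiated WT replicate 2, 0.435 without irradiated WT replicate 1, 0.331 without non-irradiated KO replicate 1 and 0.37 without irradiated KO replicate 2. Without irradiated WT replicate 1 cholesterol synthesis had -0.199 and ribosomal proteins -0.142. The counts fell to 98 to 135 and 20 to 32 when any 1 of the 8 libraries was left out.

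Lists whose call hung on single libraries were S phase (-0.151; camera adjusted p = 0.114 without non-irradiated WT replicate 2, 0.0808 and a median of -0.099 without irradiated WT replicate 1, 0.0985 without irradiated KO replicate 2) and senescence-associated factors (0.23; 0.106 and 0.151 without the same WT libraries, 0.0594 and 0.0819 without non-irradiated KO replicates 1 and 2, 0.126 without irradiated KO replicate 2; median 0.144 without irradiated KO replicate 1). With an estimated correlation these 2 lists had camera adjusted p = 0.43 and 0.291, and with fry adjusted p = 0.0876 and 0.0254. With the block and all 8 libraries they had camera adjusted p = 0.00315 and 0.0108, and YAP/TAZ targets had 0.0222. The other such lists were YAP/TAZ targets (-0.213; 0.676 with an estimated correlation, 0.297 with fry) and mitochondrially encoded genes (-0.453; 0.587 and 0.307). Without non-irradiated WT replicate 1, irradiated WT replicate 2, non-irradiated KO replicate 2 and irradiated KO replicate 1 the former had 0.17, 0.183, 0.356 and 0.156, with medians of -0.086, -0.105, -0.067 and -0.081. The latter had 0.406, 0.317, 0.264 and 0.171, with medians of -0.168, -0.117, 0.03 and -0.211.

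Among genes named by the fixed rule, which draws members from the lists that passed, the call of the following held whichever 1 library was left out. Those with a larger change in KO included Tap1 (2.877), Ifit2 (2.559), Ifih1 (2.076), Eif2ak2 (1.667), Nlrc5 (1.994), Socs1 (2.608), Psmb10 (1.346), Psmb9 (3.201), Tlr3 (2.479), Ifi203 (1.735), Samhd1 (1.215), Irf1 (1.155), Cd274 (3.044), Lgals9 (1.02) and Slfn8 (3.644). Chac1 (1.14) and Spp1 (0.95) also had a larger change in KO, and Pdgfra (-1.141), Rtl9 (-2.514) and Slc35f1 (-2.883) a smaller one. Enpp5 (7.116) had no reads in non-irradiated KO, so its fitted value depends on the prior count of the fit.

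Isg15 (2.184) lost its call without non-irradiated WT replicates 1 and 2 (0.13 and 0.0761) and non-irradiated KO replicates 1 and 2 (0.0652 and 0.067). Batf2 (4.106) lost it without non-irradiated WT replicates 1 and 2 (0.0656 and 0.0643) and irradiated KO replicates 1 and 2 (0.0571 and 0.064), and Dcn (-1.715) without non-irradiated WT replicate 2 (0.0535). Tgtp1 (4.727; edgeR adjusted p 0.0629 to 0.225) and Clstn3 (-6.42, with no reads in non-irradiated WT; 0.0558 to 0.068) lost it without any library but those of irradiated WT. Hist1h2bc (1.033; 0.0532 to 0.0697) lost it without non-irradiated WT replicate 1, irradiated WT replicate 2, non-irradiated KO replicate 1 and irradiated KO replicates 1 and 2. Trib3 (0.947; 0.0649 to 0.0775) lost it without any library but non-irradiated KO replicate 2 and irradiated KO replicate 1.

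Calls lost without any library but 1 were those of Kazn (-3.247; 0.0538 to 0.0788), Dach2 (3.364; 0.0983 to 0.176) and Hist1h1c (1.094; 0.0578 to 0.142), each kept only without non-irradiated WT replicate 2. The same held for Dlc1 (-1.048; 0.078 to 0.156; irradiated KO replicate 2), Olfr56 (3.401; 0.0526 to 0.242; non-irradiated KO replicate 1) and Plau (-1.611; 0.128 to 0.19; irradiated WT replicate 1). Without any 1 of the 8 libraries the call was lost for Ccn1 (-0.545; 0.0827 to 0.188), Csf1 (0.611; 0.0865 to 0.186), Edn2 (-2.87; 0.075 to 0.222), Itpr2 (1.058; 0.0716 to 0.166) and Lbp (-2.446; 0.0535 to 0.137). It was also lost each time for Mcm4 (-0.608; 0.0694 to 0.126), Mcm6 (0.645; 0.0695 to 0.122), Plk2 (-0.603; 0.085 to 0.206), Trpv2 (3.029; 0.0711 to 0.125) and Uhrf1 (-0.643; 0.0694 to 0.193).

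The larger interferon response to irradiation in KO could have come from the replicate difference, from a larger response of all genes or from gene dosage. In each replicate alone, with its own 4 libraries, the 87 members of the 4 interferon lists had a median interaction of 0.844 (0.544 to 1.196) and 1.177 (0.675 to 1.428), against 0.019 and -0.027 for all other genes. A replicate shift shared by all groups cancels within each replicate, so these values do not test it. They show only that the larger response was not confined to 1 replicate. Their intervals cover the spread between genes and not between libraries. Among 1454 genes outside the 4 interferon lists, rising or falling in both lines, the median ratio of the KO to the WT response was 1.011 (0.988 to 1.034). It was 1.451 (1.354 to 1.708) for 57 genes inside them that rose in WT. The gap argues against a larger response of all genes. These intervals come from resampling genes, which are not independent, and do not cover the spread between libraries. Of the 205 genes, 185 lay outside chromosomes 7, 16 and 18. These chromosomes held 5.9, 2.4 and 1.5 percent of the 205, against 7.7, 3 and 2.4 percent of tested genes. That count does not decide on dosage, since a constant dosage difference cancels in the interaction. It also covers few interferon genes, as 29 of the 205 were members of the 4 lists. Dosage of the interferon genes or of a regulator stays open. Whether the editing of Piezo2 or another difference between 2 cell lines lies behind the pattern stays open, since there was 1 edited line from 1 guide.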

How the results depend on the processing

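The alternatives were planned, except the fits without chromosomes 7, 16 and 18, without processed pseudogenes and ribosomal protein genes, and with the block without these chromosomes, which were chosen only after the results were seen. Groups of 2 libraries limit every count, and the cause of the moves below was not tested. Genes higher and lower with the block, where moved, were 4465 lower (irradiation in WT), 4417 lower (irradiation in KO), 3197 and 3504 (KO without irradiation), 3761 and 3755 (KO after irradiation) and 1216 and 1276 (interaction). The block without the 3 chromosomes gave 2654 and 2725, 3106 and 3033, and 1043 and 1159 in the last 3 comparisons. A minimum log2 change of 1 (glmTreat) left 561 and 97, 686 and 94, 142 and 119, 298 and 137, and 34 and 3 genes in the 5 comparisons. Only the compared groups gave 831 lower genes for KO without irradiation, and no filter gave 359 and 219 interaction genes. Leaving out 1 library gave 1741 to 2790 lower genes (irradiation in WT), 2008 to 3093 higher and 1738 to 2639 lower (irradiation in KO), 807 to 1395 and 689 to 1238 (KO without irradiation), 1101 to 1891 and 850 to 1626 (KO after irradiation), and 98 to 135 and 20 to 32 (interaction). Lists past the threshold with an estimated correlation numbered 5, 4, 0, 3 and 3, and 0 in every comparison when the block was added. With fry they were 11 for KO without and 18 for KO after irradiation, and without pseudogenes and ribosomal protein genes 6 in the interaction. The similarity of the irradiation responses was 0.841 with a filter of 1 CPM and 0.696 to 0.782 leaving out 1 library, and that of the KO effects 0.753, 0.765 among called genes only, and 0.541 to 0.641. Leaving out 1 library changed the sign of the median of 1 called list, that of mitochondrially encoded genes in the interaction (0.03 without non-irradiated KO replicate 2), and of no called gene named by the rule. Among uncalled genes signs changed as follows, with ranges over all 8. For irradiation in WT they were Ccng1 -0.029 to 0.064, Mki67 -0.211 to 0.172 and Mcm5 -0.075 to 0.041. For irradiation in KO they were Mdm2 -0.078 to 0.091, Ccng1 -0.101 to 0.131 and Mki67 -0.27 to 0.025. For KO without irradiation they were Ccnb1 -0.146 to 0.127, Cd274 -0.103 to 0.034, B2m -0.149 to 0.025 and H2-K1 -0.071 to 0.078 (0 in DESeq2), and for KO after irradiation Ccnb1 -0.127 to 0.142. In the interaction they were Ccng1 -0.11 to 0.101, Mki67 -0.268 to 0.116, Top2a -0.112 to 0, Ccnb1 -0.122 to 0.169, Ccl5 -0.767 to 0.741 and Piezo1 -0.132 to 0.235. The block took away no call of a named gene. Beyond those given in the report it added Mki67 for irradiation in KO (0.0116), Mdm2, Ccng1, Mki67, Cxcl10 and Piezo1 for KO without irradiation (0.00565, 0.000114, 1.81e-14, 0.0105 and 5.52e-08), Mki67, Lmnb1 and Piezo1 for KO after irradiation (3.66e-12, 0.0145 and 2.4e-06), and Cdkn1a, Mcm5 and Lmnb1 in the interaction (0.000829, 0.00088 and 1.62e-06). It changed no other call of a named gene.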

Other observations

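All genes in this part were chosen, and all its tests run, only after the results were seen. Reads of 2 type I interferon genes separated the lines after irradiation, while no list made up of such genes was tested. Ifnb1 and Cgas are members of the nucleic acid sensing list and Cxcl9 of the chemokine list. Their values below are thus already part of those list results. Ifnb1, interferon beta, had 1 and 0 reads in non-irradiated WT, 4 and 4 in irradiated WT, 1 and 0 in non-irradiated KO, and 129 and 118 in irradiated KO. Irradiated KO was above irradiated WT by 4.85 ± 0.57 on the log2 scale (edgeR adjusted p = 0.000856), while the interaction, resting on 1 read in each non-irradiated group, did not pass (4.78, 0.397). Ifna4 had 23 and 16 reads in irradiated KO and 0 in the other libraries, Ifna1 had 1 and 1 there and 0 elsewhere, and Ifng no more than 1 read in any library. Cxcl9, a T cell attractant, had 5 and 5 reads in irradiated WT, 66 and 65 in irradiated KO and 0 elsewhere. The DNA sensor Cgas was higher in irradiated KO than irradiated WT by 1.25 ± 0.21 (0.00486) and Il15ra, which presents Il15, by 0.78 ± 0.14 (0.00687).

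The gene Txnip, a thioredoxin inhibitor, rose by 5.33 ± 0.14 in WT and 3.66 ± 0.12 in KO after irradiation, with an interaction of -1.67 ± 0.17 (edgeR adjusted p = 0.00336). Trp53 was lower in KO, by 0.39 without and 0.55 after irradiation (0.0118 and 0.0021). Irradiated libraries held more genes: thinned to 10 M reads, 20848 (SD 163) were detected against 18111 (SD 326) in non-irradiated ones, a difference of 2736. An exact permutation test that swapped doses only within line and replicate number gave a two-sided p = 0.125, the smallest that 16 swaps allow.

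The shifts of chromosomes 7, 16 and 18 between the lines could have come from base composition, from a few strongly changed genes or from copy number. Genes of other chromosomes matched to those of chromosome 7 on GC content and level had a median of -0.054 (-0.083 to -0.03) without irradiation, against 0.372, and those matched to 16 and 18 -0.04 and -0.025, against -0.35 and 0.427. Of 32 windows of 40 genes on these chromosomes 31 had the sign of their chromosome in both comparisons, and both results argue against the first explanations. Irradiation moved the medians of these chromosomes by no more than 0.095 in either line, which is consistent with different copy number of the lines, a hypothesis that DNA sequencing or karyotypes of both lines would test. Chromosome 18 carries Piezo2, and whether its shift is tied to the editing stays open.

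The replicate 1 and replicate 2 libraries differed in every group, at 5103 genes (2577 higher and 2526 lower in replicate 2). Processed pseudogenes had a median of 1.395 (660 genes), against -0.034 (-0.063 to -0.003) for genes matched on GC content and level, and took 0.115 to 0.147 percent of counts in replicate 1 and 0.27 to 0.332 percent in replicate 2. Over the other genes the replicate effect and GC content correlated at Spearman rho = 0.377. Different counting of reads shared by gene copies and GC bias may both be part of it, and no biological explanation was tested.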
